A study of Mus musculus with 40 samples.

How the data were processed

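Liver RNA of male C57BL/6J mice was measured on Illumina mouse expression BeadChips, 1 array per sample. Per the labels' protocols, RNA was extracted with Trizol, checked by Nanodrop and Bioanalyzer, and 0.5 µg of total RNA was amplified into biotin-labelled cRNA. The mice arrived at 6 weeks of age, began the diets at 5 months, and the portions of the CR and MF groups were fixed at 14 months. Per the labels, CR mice were fed on the cage floor and the others from the hopper. Groups were taken from the labels: 5 AL-NIA, 9 CR-NIA, 6 MF-NIA, 6 AL-WIS, 10 CR-WIS and 4 MF-WIS arrays. The series text states 48 arrays, and the 40 given here were analysed.

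The deposited value table holds a score per probe and array. From its values, each array is a z-score with mean 0 and SD 1, and the authors' steps behind it are not given in the sources used here. The deposited signal table holds a linear signal intensity per probe, made with GenomeStudio 2011.1 per the submitters' processing notes. It also holds a detection p-value per probe beside each intensity, per the file headers. The header gives the group of each signal column but not the sample. It counts 6 AL-NIA and 8 CR-NIA columns where the labels give 5 and 9 samples. The 6 AL-NIA columns were therefore not used in any step, and 34 columns were. For 34 samples a column of the same group matched the scores within 0.01; for the library labelled CR-NIA replicate 1 none did (smallest largest difference 3.17). That library stayed in the group of its label.

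The plan assumed log2 intensities with neqc, limma's background correction and quantile normalization. Since columns could not be matched to samples by name, the fallback written in the plan was used: the score table with limma. Scores were multiplied by 1.51, the median over 34 columns of the SD of the log2 signal, so that differences read in log2 units. Against the log2 signals, the slope of differences was 0.968 for CR against AL in WIS, 0.968 for CR against MF in WIS and 0.999 for WIS against NIA under MF. All folds rest on this rescaling, and without background subtraction they understate changes of dim genes.

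Probes were kept with a detection p-value under 0.01 on at least 4 of the 34 arrays, which left 11334. AL-NIA arrays could not enter this filter. Gene names came from the platform annotation: 23978 probes had 1 symbol, 1719 none and 0 several, and 0 symbols changed when updated through gene identifiers. The brightest probe stood for each of 7958 genes, of which 1993 had several. No genome coordinates are given. Near-identical families (Cyp2a, Cyp2b, Cyp2c, Cyp3a, lysozymes, S100a, Gst) can share probes. Detection ranged from 34.0% to 43.6% of probes and median signals from 134 to 276, and the number of arrays limits the precision.

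A limma 3.58.1 model (R 4.3.3) with 1 mean per group was fitted over 40 arrays, with Benjamini-Hochberg adjustment at 0.05 in each of 9 comparisons and 2 interactions. Each p-value of a gene is limma's adjusted p. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 40 of 41 lists with at least 5 measured genes; of 985 genes in lists 983 matched a gene and 725 were measured. No list call described held with a correlation estimated from the data. A gene detected on no array of a group is given as a bound, the brighter group's mean against the detection floor of the dimmer group. A gene detected on part of a group's arrays is given by its measured fold, which then rests in part on background signal. Other probes of a named gene are given where they did not pass, with p adjusted over all 10659 probes that passed the filter and have a gene.

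Groups, models, lists, the filter and the rule for named genes were fixed before the data were examined. That rule takes the 10 largest rises and 10 largest falls past the threshold in each comparison, up to 4 members with the smallest p of each list described, and the 10 smallest adjusted p of each interaction. Which lists to describe was decided after the values were seen. Genes whose call ended on removal of more than 4 single libraries were mostly left out, also decided then. Data were simulated with each gene's mean and 1 spread for all groups, genes being independent and no library outlying. There, a log2 difference of 1 was recovered for 94.0% of changed genes in CR against AL in NIA and 91.0% in MF against AL in WIS. It was 86.6% in WIS against NIA under MF and 85.1%, the lowest, in CR against MF in WIS, each among 7958 genes. A difference of 0.5, near the median size of called differences in CR against AL (0.51 in NIA and 0.50 in WIS), was recovered for 61.2%, 55.2%, 49.3% and 53.7%. False calls numbered 8, 12, 7 and 8. The real arrays hold libraries that stand apart and genes that move together, so recovery and false calls there can be worse.

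Alternatives were neqc, quantile normalization alone, median scaling, other filters, the mean of probes, array weights, trended and robust moderation, only the groups compared, the replicate number as a block, each library left out, an estimated correlation and fry. Leaving out 3 libraries together, and neqc over the 5 groups whose signals could be used, were added after seeing the data. Neqc, quantile normalization and median scaling used the 34 signal columns only. These hold no AL-NIA arrays and 8 CR-NIA columns, none of which matched the library labelled CR-NIA replicate 1. A change under these settings thus mixes the scaling with a change of arrays.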

Results

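Liver RNA of 40 male C57BL/6J mice, an inbred laboratory strain, was measured on an Illumina mouse expression BeadChip, a microarray in which bead-bound probes capture labelled copies of single transcripts. The mice had eaten 1 of 2 diets from 5 months of age. The NIA diet took 7.6% of its energy from sucrose and 17.7% from fat, and the WIS diet 46% and 24.4%. Each diet was given under 3 regimens: ad libitum (AL), caloric restriction by 30% (CR), and meal feeding (MF). Both CR and MF mice received their food in a single daily portion at 3 pm. The comparisons thus bear on how much was eaten, when it was eaten and what it was made of. The groups held 5 AL-NIA, 9 CR-NIA, 6 MF-NIA, 6 AL-WIS, 10 CR-WIS and 4 MF-WIS arrays, 1 per liver. Per array, 8725 to 11199 of the 25697 probes were detected on the 34 arrays whose detection p-values were used, and 7958 genes were tested. The number of arrays per group limits the precision. The labels used here give neither the hour of tissue collection nor the time since the last meal, which bears on every clock and feeding gene below.

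The first principal component held 30.5% of the variance. It was led by a single library, AL-WIS replicate 1, at a score of 82.1, against 21.4 for the next highest. In that library the macrophage and Kupffer cell markers lay 3.41 log2 units above their mean over all libraries, and the neutrophil markers lay 2.81 above. In AL-WIS replicate 1 the hepatocyte markers were 0.61 lower in the median than in the other 5 AL-WIS libraries (-0.61, SE 0.28 over 17 markers). The library labelled CR-NIA replicate 1 had a clock list score of -0.73, against 0.19 to 0.50 in the other 8 CR-NIA libraries and -0.77 to 0.18 in AL-NIA. MF-WIS replicate 4 had the highest scores of all 40 libraries for NRF2 and glutathione genes, at 1.83, and for bile duct cell (cholangiocyte) markers, at 1.35. All 3 were kept. Each count of changed genes is also given without them, a choice made after seeing the data.

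**Figure D1:**
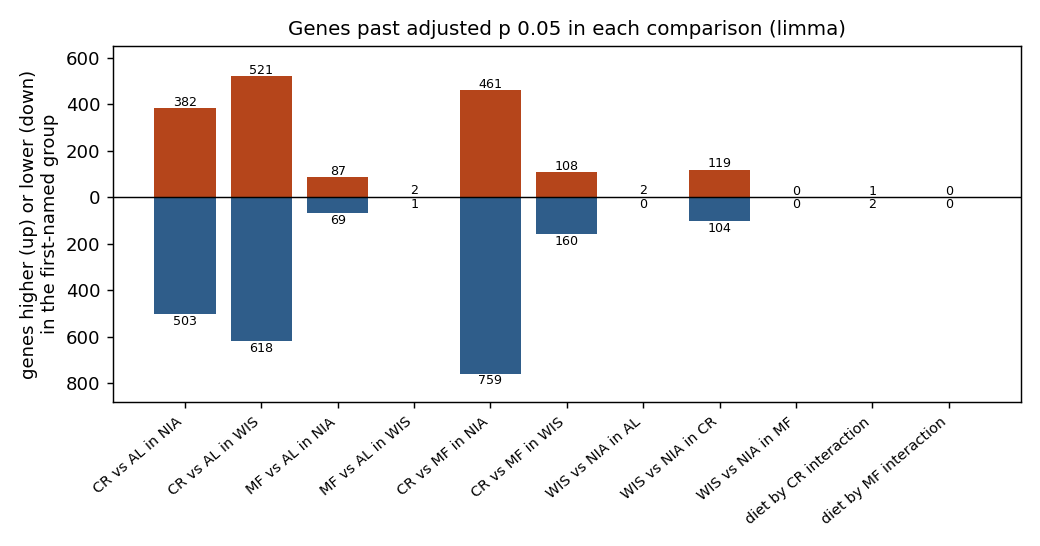
Number of genes past an adjusted p of 0.05 (limma, 7958 genes, 40 arrays) in each comparison; bars above 0 count genes higher in the first-named group and bars below 0 genes lower in it. CR against MF in NIA had 461 genes higher and 759 lower, and WIS against NIA under MF had 0.

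Caloric restriction on the NIA diet was compared with ad libitum feeding to show what eating less, in 1 daily portion, did on the low-sucrose diet. Genes of the circadian clock were among the largest changes. Usp2, a deubiquitinase with daily rhythm, rose by a measured 8.38-fold (log2 3.07, SE 0.59, adjusted p = 0.000994, n = 9 CR and 5 AL), and 8 of 9 CR libraries lay above all AL libraries. Detection was not read in AL-NIA, and 3 of its 5 libraries lay for Usp2 at or below -0.44, the mean of the lowest detected levels of the 34 arrays, so this fold is taken against signals partly at background. The clock-output factors Dbp and Tef rose 7.89-fold (log2 2.98, SE 0.77, adjusted p = 0.00996) and 3.25-fold (SE 0.37, adjusted p = 0.00311). Nfil3, a repressor acting on the same promoters, was 4.17-fold lower (log2 -2.06, SE 0.39, adjusted p = 0.000985). By other probes of Usp2 and Tef the rise was smaller: log2 0.86 (adjusted p = 0.00206) and 0.25 (adjusted p = 0.0951) for Usp2, and 0.19 (adjusted p = 0.187) for Tef. Of 15 measured clock genes 8 rose, 3 fell and 4 did not pass, and 9 rose and 3 fell adjusted over the list alone. The list test gave adjusted p = 0.0128, and adjusted p = 0.774 with an estimated correlation.

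Among other genes of CR on NIA, Angptl4, a fasting-induced inhibitor of lipoprotein lipase, rose 3.51-fold (log2 1.81, SE 0.40, adjusted p = 0.00311). Gpcpd1, a glycerophosphodiesterase, rose 4.16-fold (SE 0.46, adjusted p = 0.00335), and Coq10b, a coenzyme Q-binding protein, rose 3.61-fold (SE 0.36, adjusted p = 0.000994). Both calls rest on 1 of 2 probes, the other lying at log2 0.48 for Gpcpd1 (adjusted p = 0.181) and 0.88 for Coq10b (adjusted p = 0.0771). The steroid hydroxylase gene Cyp17a1, detected on 4 of the 8 CR-NIA arrays read, was 6.11-fold lower (log2 -2.61, SE 0.62, adjusted p = 0.00547). The tubulin gene Tubb2b was 5.58-fold lower (SE 0.45, adjusted p = 0.000703) by 1 probe and at log2 -0.21 (adjusted p = 0.416) by its other probe. Insig2, which holds the sterol-sensing SREBP complex in the endoplasmic reticulum, was 3.31-fold lower (SE 0.35, adjusted p = 0.00158).

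Of 21 unfolded protein response genes, 0 rose and 5 fell in CR-NIA, or 7 adjusted over the list alone. Without CR-NIA replicate 1, 8 fell, and without the 3 libraries that stood apart 10 fell and 1 rose. Creld2, induced by endoplasmic reticulum stress, was 3.08-fold lower (log2 -1.63, SE 0.29, adjusted p = 0.000663). The ubiquitin ligase Syvn1 was 1.75-fold lower (SE 0.19, adjusted p = 0.00469) and the transcription factor Atf4 1.61-fold lower (SE 0.18, adjusted p = 0.0109). The list had adjusted p = 0.00113, and adjusted p = 0.894 with an estimated correlation. Of 20 heat shock and chaperone genes 3 fell, or 4 adjusted over the list alone. They included the HSP90 co-chaperone Ahsa1 (1.44-fold, SE 0.12, adjusted p = 0.00462) and the chaperonin subunit Cct3 (1.36-fold, SE 0.12, adjusted p = 0.014). In the list test the adjusted p was 0.0212, and adjusted p = 0.894 with an estimated correlation. Without AL-NIA replicate 5 the list p was 0.126, with the replicate number as a block 0.0712. Without CR-NIA replicate 1, 6 of the 20 genes fell and 1 rose, and without the 3 libraries 7 fell and 1 rose.

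Of 68 oxidative phosphorylation genes 13 rose in CR-NIA and 0 fell, or 22 rose adjusted over the list alone. They included Ndufv2 of complex I (1.45-fold, log2 0.54, SE 0.11, adjusted p = 0.00178) and the ATP synthase subunit Atp5j2 (1.58-fold, SE 0.15, adjusted p = 0.00327). As a set they had adjusted p = 4.88e-09, and adjusted p = 0.894 with an estimated correlation. Without CR-NIA replicate 1, 23 of the 68 genes rose, and 29 without the 3 libraries that stood apart. The mean difference between probes of 1 gene, described under CR against MF, was 0.48 in CR-NIA and -0.12 in AL-NIA. Its genes were chosen by CR-NIA against MF-NIA, so a high CR-NIA value follows in part from that choice. Of 20 macrophage markers 0 passed (median log2 -0.55; list adjusted p = 0.0128, and adjusted p = 0.894 with an estimated correlation); 7 fell without AL-WIS replicate 1 and 4 without CR-NIA replicate 1. Of 19 CAR and PXR genes 3 rose, or 5 adjusted over the list alone (list adjusted p = 0.0339, and adjusted p = 0.894 with an estimated correlation). That list lost its call without AL-NIA replicate 3 or 4 or CR-NIA replicate 1, 2 or 8 (highest adjusted p = 0.194).

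In all, 885 genes changed in CR-NIA against AL-NIA, 382 higher and 503 lower (limma, adjusted p under 0.05), and 2139 without the 3 libraries that stood apart. Without CR-NIA replicate 1 alone there were 1422, and without AL-NIA replicate 4 there were 507. Dbp lost its call without AL-NIA replicate 4 or 5 (highest adjusted p = 0.061).

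Caloric restriction on the WIS diet was compared with ad libitum feeding on the same sucrose-rich food. Usp2 rose 8.23-fold (log2 3.04, SE 0.54, adjusted p = 0.00218, n = 10 CR and 6 AL) and lay above all AL-WIS libraries in 9 of 10; it was detected on 4 of 6 AL-WIS arrays, and its other probes rose by log2 0.88 and 0.33. Dbp rose 7.02-fold (SE 0.71, adjusted p = 0.00995), Ciart, a clock repressor, 4.16-fold (SE 0.35, adjusted p = 0.00218), and Per2 2.48-fold (SE 0.27, adjusted p = 0.00312). Of 15 clock genes 8 rose and 3 fell, or 9 and 3 adjusted over the list alone. The set test gave adjusted p = 0.000305, and adjusted p = 0.378 with an estimated correlation. Alas1, the first enzyme of heme synthesis, rose 3.64-fold (SE 0.39, adjusted p = 0.00364). Coq10b rose 3.57-fold (SE 0.33, adjusted p = 0.00218), and Inmt, an indolethylamine methyltransferase, 3.47-fold (log2 1.79, SE 0.45, adjusted p = 0.00977), or log2 1.01 without AL-WIS replicate 1. Cyp17a1 was 5.67-fold lower (log2 -2.50, SE 0.57, adjusted p = 0.00652).

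Metabolic gene lists also moved up in CR-WIS, in part through AL-WIS replicate 1, which is in the AL mean. Of 12 gluconeogenesis genes 6 rose, or 9 adjusted over the list alone. They included the transcription factors Klf15 (1.71-fold, SE 0.16, adjusted p = 0.00273) and Foxo1 (1.44-fold, SE 0.12, adjusted p = 0.0073). Tested as a list, they had adjusted p = 8.86e-06, and adjusted p = 0.501 with an estimated correlation; without AL-WIS replicate 1, 2 members rose. Of 28 PPAR-alpha, fatty acid oxidation and ketogenesis genes 6 rose, or 10 with 1 falling adjusted over the list alone. Among them were Pex11a of peroxisome division (1.89-fold, SE 0.26, adjusted p = 0.0196) and the acyl-CoA dehydrogenase Acadvl (1.49-fold, SE 0.17, adjusted p = 0.0203). Of the other 2 probes of Pex11a, 1 missed the threshold (log2 0.63, adjusted p = 0.0518) and 1 passed it (log2 1.12). For the whole list the adjusted p was 8.86e-06, and adjusted p = 0.628 with an estimated correlation, and 0 members passed (limma) without AL-WIS replicate 1. Of 68 oxidative phosphorylation genes 16 rose, or 24 adjusted over the list alone, such as Cyc1 (1.41-fold, SE 0.11, adjusted p = 0.00577) and Ndufs7 (1.36-fold, SE 0.10, adjusted p = 0.00702). That list had adjusted p = 1.2e-12, and adjusted p = 0.547 with an estimated correlation; without AL-WIS replicate 1, 3 rose and the median was log2 0.15 instead of 0.27. The mean probe difference described under CR against MF was 0.15 in CR-WIS and -0.11 in AL-WIS.

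The bile acid list had 5 of 17 members higher in CR-WIS, or 6 adjusted over the list alone, among them the sterol exporter genes Abcg5 (2.09-fold, SE 0.27, adjusted p = 0.011) and Abcg8 (2.19-fold, SE 0.30, adjusted p = 0.0141). The list had adjusted p = 0.00294, and adjusted p = 0.628 with an estimated correlation. The list of CAR and PXR, the xenobiotic receptors, and their targets had 5 of 19 members higher, and 5 adjusted over the list alone. They included the receptor genes Nr1i3 (2-fold, SE 0.25, adjusted p = 0.0104) and Nr1i2 (1.7-fold, SE 0.19, adjusted p = 0.00881) and the hydroxylase gene Cyp2a5 (3.25-fold, SE 0.41, adjusted p = 0.00836). In the list test the adjusted p was 0.00837, and adjusted p = 0.628 with an estimated correlation. Without AL-WIS replicate 1 the list p was 0.446 for bile acids, with 0 members higher and 1 lower (limma). The bile acid median was then log2 0.11 instead of 0.31. For CAR and PXR the list p was 0.54, with 2 members higher and 1 lower and a median of -0.003 instead of 0.44. Without that library Abcg5, Abcg8, Nr1i3, Nr1i2, Pex11a and Acadvl lost their calls (adjusted p 0.0567, 0.0692, 0.0584, 0.0506, 0.0978 and 0.101). Their log2 differences were then 0.66, 0.65, 0.72, 0.56, 0.67 and 0.31.

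Part of the macrophage, stellate cell and neutrophil markers were lower in CR-WIS than in AL-WIS, in part through AL-WIS replicate 1, while of 21 endothelial markers 2 fell (list adjusted p = 0.361). Of 20 macrophage and Kupffer markers 16 fell, or 17 adjusted over the list alone. The lysozyme gene Lyz2 was 3.42-fold lower (log2 -1.77, SE 0.38, adjusted p = 0.00471) and Adgre1, which encodes F4/80, 3.05-fold lower (SE 0.38, adjusted p = 0.00791). As a set they had adjusted p = 2.4e-08, and adjusted p = 0.547 with an estimated correlation. Of 23 stellate cell and fibrosis genes 13 fell, or 21 adjusted over the list alone, such as the growth factor receptor Pdgfra (1.54-fold, SE 0.15, adjusted p = 0.00702) and the collagen gene Col3a1 (1.81-fold, SE 0.20, adjusted p = 0.00748). That list had adjusted p = 4.05e-09, and adjusted p = 0.547 with an estimated correlation. Of 8 neutrophil markers 4 fell, or 6 adjusted over the list alone, S100a8 among them (3.78-fold, SE 0.54, adjusted p = 0.0182), with list adjusted p = 0.00326, and adjusted p = 0.628 with an estimated correlation. Of 23 interferon genes 6 fell, or 7 adjusted over the list alone, Ifit2 among them (1.37-fold, SE 0.11, adjusted p = 0.00797), with list adjusted p = 0.0104, and adjusted p = 0.628 with an estimated correlation. Without AL-WIS replicate 1, 3 macrophage, 3 stellate, 0 neutrophil (limma) and 1 interferon gene still fell. The macrophage median was then log2 -0.67 instead of -1.29, the stellate median -0.37 instead of -0.51 and the neutrophil median -0.32 instead of -0.84. The neutrophil list then had adjusted p = 0.048, and lost its call without the 3 libraries (adjusted p = 0.0761), where 8 macrophage and 6 stellate genes fell. S100a8 lost its call without AL-WIS replicate 1 or 5 (highest adjusted p = 0.0962).

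In all, 1139 genes changed in CR-WIS against AL-WIS, 521 higher and 618 lower, and 762 without the 3 libraries. Without AL-WIS replicate 1 there were 423, without AL-WIS replicate 5 695, without CR-WIS replicate 1 757, and 362 when only the groups compared were fitted. The share of higher calls, 45.7%, was 53.8% after neqc of the signals, 54.8% with quantile normalization, 51.8% without the detection filter, 56.4% when only the groups compared were fitted, 54.8% with the replicate number as a block and 50.6% without AL-WIS replicate 1.

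The effects of CR in NIA and in WIS, which share no arrays, were set side by side over all genes. Their correlation across 7958 genes, which are not independent replicates, was 0.65, and 0.75 over the 1750 genes called in either. Of the called genes 135 were higher in both, where 25 would be shared by independent lists, and 136 lower in both against 39.1. In opposite directions, 3 were called. Both lists come from the same fit with a shared spread per gene, so genes of low spread pass more easily in both. The numbers for independent lists are thus only a rough guide. The correlation of 0.75 is over genes chosen by these same effects. Usp2, Dbp and Coq10b were among those higher in both, and Cyp17a1 was lower in both.

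**Figure D2:**
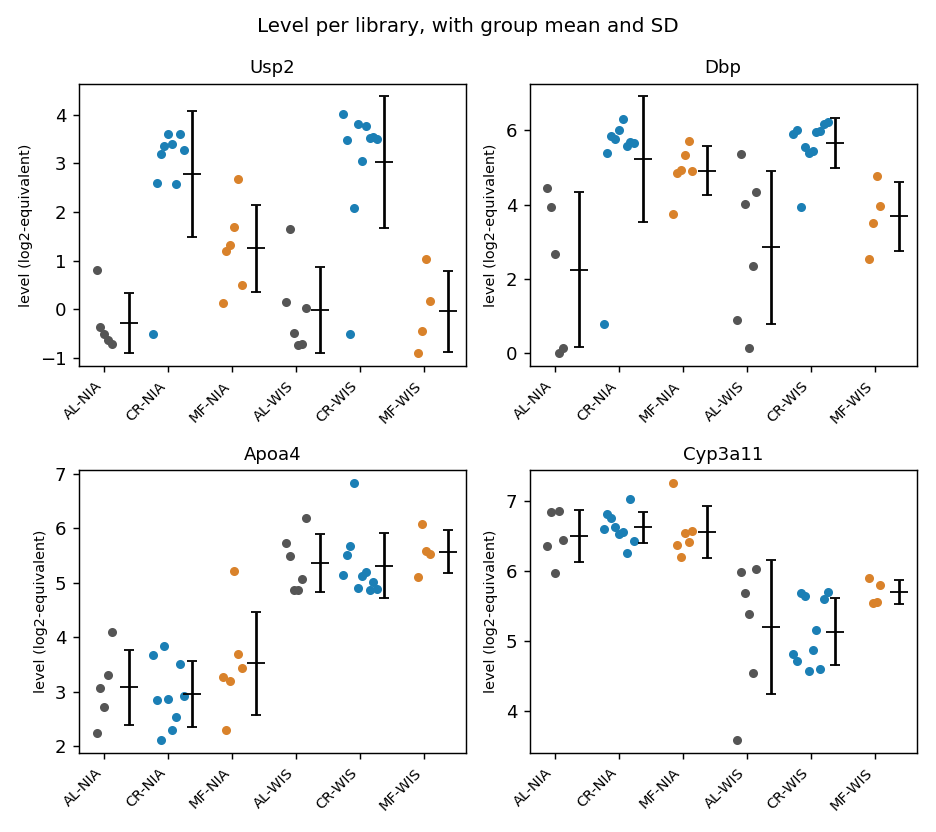
Level of 4 genes in each of the 40 libraries (y axis, z-score times 1.51, in log2 units; x axis, group), with the group mean and SD at the right of the points. Usp2 and Dbp lie above all AL libraries of the same diet in 8 of 9 CR-NIA and 9 of 10 CR-WIS libraries, and under CR all 10 WIS libraries lie above the NIA libraries for Apoa4 and below them for Cyp3a11.

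Meal feeding on the NIA diet was compared with ad libitum feeding to ask what a single daily meal did. Per the labels, AL-NIA mice ate more calories than any other group, and MF-NIA mice ate as many as AL-WIS and MF-WIS mice, so this pair differs in intake too. Angptl4 rose 4.09-fold (log2 2.03, SE 0.43, adjusted p = 0.0162, n = 6 MF and 5 AL), above all AL libraries in 6 of 6. Gys2, the liver glycogen synthase, rose 2.53-fold (SE 0.31, adjusted p = 0.0244). Pcyt1a, the rate-setting enzyme of phosphatidylcholine synthesis, was 1.79-fold lower (log2 -0.84, SE 0.19, adjusted p = 0.0244), and Slc35b1, a nucleotide sugar transporter gene, 1.75-fold lower (SE 0.18, adjusted p = 0.0187). Of 15 clock genes 0 passed over all genes (limma; 1371 of all genes had an unadjusted p under 0.05), while 9 rose and 2 fell adjusted over the list alone. Dbp, at 6.38-fold above AL (SE 0.83), had adjusted p = 0.0768 and Per2, at 1.93-fold (SE 0.31), adjusted p = 0.093; the other probe of Per2 passed (log2 0.94, adjusted p = 0.0435). The clock list had adjusted p = 0.00735, and adjusted p = 0.497 with an estimated correlation.

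Of 21 unfolded protein response genes 2 fell in MF-NIA, or 4 adjusted over the list alone: the chaperone gene Hsp90b1 (1.4-fold, SE 0.12, adjusted p = 0.032) and Selenos, a factor of endoplasmic reticulum-associated degradation (1.53-fold, SE 0.15, adjusted p = 0.0352), whose other probe lay at log2 -0.43 (adjusted p = 0.0666). The set test gave adjusted p = 0.000141, and adjusted p = 0.497 with an estimated correlation. Without AL-WIS replicate 1, 4 of the 21 genes fell, and without CR-NIA replicate 1, 3 did, though neither library is in this pair. Of 28 PPAR-alpha and fatty acid oxidation genes 2 rose, or 3 adjusted over the list alone, Angptl4 being 1 of them. Tested as a list, they had adjusted p = 0.0125, and adjusted p = 0.885 with an estimated correlation; its p reached 0.169 without AL-NIA replicate 1, AL-NIA replicate 4 or MF-NIA replicate 1. Of 17 hepatocyte markers 16 lay below AL with a median log2 of -0.44 and 0 passed (limma), also adjusted over the list alone. The mean probe difference described under CR against MF was -0.59 in MF-NIA and -0.12 in AL-NIA. A low MF-NIA value follows in part from the choice of its genes. The hepatocyte list adjusted p was 7.68e-06, and adjusted p = 0.665 with an estimated correlation. The transferrin gene Trf was at 1.58-fold below AL (SE 0.23, adjusted p = 0.127).

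In all, 156 genes changed in MF-NIA against AL-NIA, 87 higher and 69 lower, and 529 without the 3 libraries. The share of higher calls, 55.8%, was 41.1% without the detection filter. This count rested on single libraries: without AL-NIA replicates 1, 2, 3, 4 or 5 it was 5, 85, 94, 80 or 1, and without MF-NIA replicates 2, 3 or 6 it was 39, 39 or 38. The count was 298 without AL-WIS replicate 1. Angptl4 and Slc35b1 lost their calls without AL-NIA replicate 1 or 5 (highest adjusted p 0.0533 and 0.0656). Gys2 lost its call also without AL-NIA replicate 4 or MF-NIA replicate 3, Pcyt1a without MF-NIA replicate 2 or 6 (highest adjusted p 0.0763 for both). Hsp90b1 lost its call without AL-NIA replicate 1, 2 or 5 or MF-NIA replicate 2, 3 or 6 (highest adjusted p = 0.0763), and Selenos without AL-NIA replicate 1, 2, 4 or 5 or MF-NIA replicate 2, 3 or 4 (highest adjusted p = 0.086).

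Meal feeding on the WIS diet was compared with ad libitum feeding at a calorie intake that the labels give as equal. Of 7958 genes 3 passed. Chp2, a calcineurin-related protein, was not detected on any of the 4 MF-WIS arrays and on 4 of 6 AL-WIS arrays, at least 1.2-fold lower (adjusted p = 0.0125). Ermard, a membrane protein of the endoplasmic reticulum, rose 1.4-fold (log2 0.48, SE 0.10, adjusted p = 0.0284), and Gm5347, a predicted gene named because the count is small, lay higher (log2 0.52, SE 0.10, adjusted p = 0.019). Of 20 NRF2 and glutathione genes 0 passed over all genes, while 9 rose and 1 fell adjusted over the list alone. They included Srxn1, which reduces peroxiredoxins, at 2.11-fold (SE 0.28, adjusted p = 0.128), and the quinone reductase Nqo1 at 1.97-fold (SE 0.29, adjusted p = 0.161). Neither passed, and without MF-WIS replicate 4 Srxn1 lay at log2 0.45 instead of 1.08 and Nqo1 at 0.29 instead of 0.98. For the whole list the adjusted p was 1.07e-06, and adjusted p = 0.52 with an estimated correlation, and without MF-WIS replicate 4 it had adjusted p = 0.177. Of 20 macrophage markers 0 passed over all genes and 13 fell adjusted over the list alone, at a median log2 of -1.19. Clec4f, a Kupffer cell lectin, was at 3.46-fold below AL (SE 0.44, adjusted p = 0.0957). The list had adjusted p = 9.91e-11, and adjusted p = 0.52 with an estimated correlation, and its median was -0.63 without AL-WIS replicate 1.

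The limma count for MF-WIS against AL-WIS was 3, with 1177 genes at an unadjusted p under 0.05, and 5 without the 3 libraries. It was 8, 1 and 0 without AL-WIS replicates 2, 4 and 5, 5, 15 and 6 without MF-WIS replicates 2, 3 and 4, and 5 without MF-NIA replicate 1. Chp2 lost its call without AL-WIS replicate 5 (adjusted p = 0.0542), and Ermard without AL-WIS replicate 1, 4, 5 or 6 or MF-WIS replicate 1 or 4 (highest adjusted p = 0.14).

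**Figure D3:**
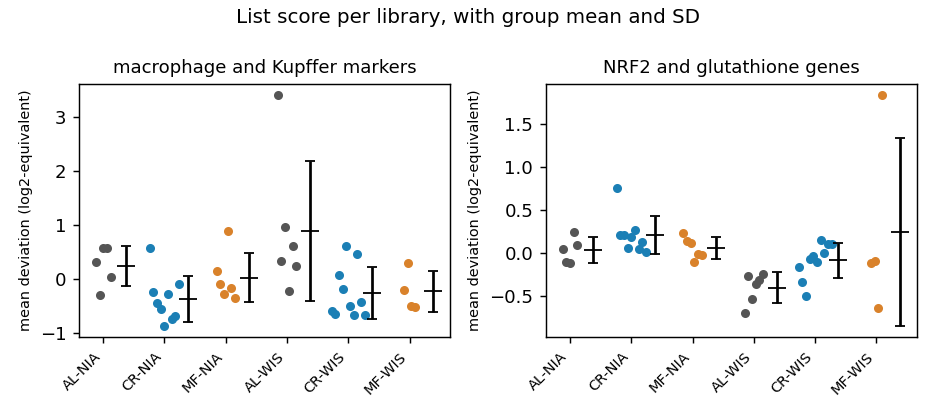
Mean deviation of 20 macrophage and Kupffer markers (left) and 20 NRF2 and glutathione genes (right) from their mean over all 40 libraries (y axis, log2 units), per library and group, with the group mean and SD. AL-WIS replicate 1 is at 3.41 on the left and MF-WIS replicate 4 at 1.83 on the right.

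Caloric restriction and meal feeding on NIA were compared to separate eating less from eating in 1 meal. Per the labels, CR mice were fed on the cage floor and MF mice from the hopper. On both diets CR and MF thus differ in this too, and it cannot be told apart from eating less. Psmd13, a proteasome lid subunit, rose 1.99-fold in CR (log2 0.99, SE 0.12, adjusted p = 3.9e-06, n = 9 CR and 6 MF), with 9 of 9 CR libraries above all MF libraries. Bst2, a virus-tethering membrane protein, rose 2.68-fold (SE 0.31, adjusted p = 0.00191), and Hsd17b11, a lipid droplet dehydrogenase, 2.08-fold (SE 0.22, adjusted p = 0.00094). The cell cycle regulator Ccnd1 rose 2.04-fold (SE 0.29, adjusted p = 0.0132) and Rbm3, a cold-induced RNA-binding protein, 2.09-fold (SE 0.32, adjusted p = 0.0198). Nsdhl, an enzyme of cholesterol synthesis, was 2.73-fold lower (log2 -1.45, SE 0.29, adjusted p = 0.000748), Hacl1, of peroxisomal alpha-oxidation, 2.52-fold lower (SE 0.31, adjusted p = 0.00301), and Insig2 2.48-fold lower (SE 0.33, adjusted p = 0.00615). Gnas, the stimulatory G protein subunit, was 2.46-fold lower (log2 -1.30, SE 0.20, adjusted p = 7.56e-05), and Plpbp, a pyridoxal phosphate-binding protein, 2.46-fold lower (SE 0.19, adjusted p = 4.5e-05).

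Part of the genes of the respiratory chain, the ribosome and the proteasome were higher in CR-NIA than in MF-NIA. The mean probe difference described below was 0.48 in CR-NIA and -0.59 in MF-NIA, a direction fixed by the choice of its genes. Of 68 oxidative phosphorylation genes 29 rose and 0 fell, or 34 rose adjusted over the list alone, Ndufv2 (1.56-fold, SE 0.10, adjusted p = 0.000112) and the complex III subunit Uqcr10 (1.55-fold, SE 0.14, adjusted p = 0.00174) among them. In the list test the adjusted p was 1.42e-16, and adjusted p = 0.484 with an estimated correlation. Of 53 cytosolic ribosomal protein genes 27 rose and 1 fell, or 34 and 1 adjusted over the list alone. Rps14 rose 1.76-fold (SE 0.15, adjusted p = 0.000384) and Rps9 1.57-fold (SE 0.13, adjusted p = 0.000647); list adjusted p = 2.8e-18, and adjusted p = 0.427 with an estimated correlation. Of 29 proteasome genes 12 rose, or 13 adjusted over the list alone, such as Psma7 (1.31-fold, SE 0.07, adjusted p = 0.000623), with list adjusted p = 1.58e-06, and adjusted p = 0.427 with an estimated correlation. Of 17 hepatocyte markers 8 rose, or 12 adjusted over the list alone, among them the plasma protein gene Ahsg (1.6-fold, SE 0.20, adjusted p = 0.0155). As a set they had adjusted p = 1.58e-06, and adjusted p = 0.591 with an estimated correlation. Of 18 antioxidant enzyme genes 6 rose and 1 fell, or 8 and 1 adjusted over the list alone, with the peroxiredoxin gene Prdx1 at 1.51-fold (SE 0.14, adjusted p = 0.00249). That list had adjusted p = 0.00179, and adjusted p = 0.427 with an estimated correlation. After neqc and with quantile-normalized signals the hepatocyte, proteasome and antioxidant lists lost their calls, the antioxidant list also with median scaling and without the detection filter, and Prdx1 lost its call under all 3 scalings. These scalings lacked CR-NIA replicate 1, but leaving it out of the main fit ended none of these list calls. After neqc the medians shrank from log2 0.54 to 0.10 for hepatocyte markers, 0.32 to 0.20 for oxidative phosphorylation, 0.39 to 0.21 for ribosomal proteins, 0.17 to 0.09 for the proteasome and 0.24 to 0.17 for antioxidant enzymes. With median scaling the hepatocyte median was 0.27. The other probe of Prdx1 lay at log2 0.15 (adjusted p = 0.567) and that of Rps9 at 0.42 (adjusted p = 0.0708). Ahsg lost its call without MF-NIA replicate 3 (adjusted p = 0.0672).

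In this comparison some probes of the same gene went opposite ways. Of 261 genes with 2 or more called probes, 17 had probes called both higher and lower (6.51%), against 0 of 162 in CR-WIS against AL-WIS (Fisher's exact test, p = 0.000423) and 1 of 135 in CR-NIA against AL-NIA, which shares the CR-NIA libraries (p = 0.00891). In CR-WIS against MF-WIS it was 0 of 36 (p = 0.24). These tests were chosen after the counts were seen. For Actb, which encodes beta-actin, 2 probes were higher in CR (log2 1.94 and 1.98, SE 0.35 and 0.37) and another lower (log2 -1.31, SE 0.31). The kininogen gene Kng1 had 2 probes higher (log2 0.65 and 0.78) and 1 lower (log2 -0.74). These 17 genes were chosen after their values were seen, and their probes were signed by the calls in CR-NIA against MF-NIA. A high CR-NIA and a low MF-NIA value thus follow from that choice, which the means of the WIS and AL groups did not enter. The mean probe difference of the 17 genes was 0.48 ± 0.38 in CR-NIA (SD, n = 9) and -0.59 ± 0.08 in MF-NIA (n = 6). In WIS it was 0.15 ± 0.17 in CR-WIS (n = 10) and -0.27 ± 0.22 in MF-WIS (n = 4). It was -0.12 ± 0.18 in AL-NIA (n = 5) and -0.11 ± 0.14 in AL-WIS (n = 6). Among the genes named in the text, Hnrnpk, an RNA-binding protein, was 2.37-fold lower (SE 0.23, adjusted p = 0.000363) by the probe used and at log2 0.08 (adjusted p = 0.63) by its other probe. A probe also did not pass for Plpbp (log2 -0.06, adjusted p = 0.698; 2 others passed), Nsdhl (log2 -0.25, adjusted p = 0.347; 3 others passed) and Hsd17b11 (log2 0.18, adjusted p = 0.124; 2 others passed).

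In all, 1220 genes changed in CR-NIA against MF-NIA, 461 higher and 759 lower, and 2328 without the 3 libraries; leaving out any 1 of 40 libraries kept the count between 877 and 1643. The share of higher calls, 37.8%, was 59.4% after neqc of the signals, 59.9% with quantile normalization alone, 64.1% without the detection filter and 19.7% with median scaling, which moved the median of all genes to -0.15. The neqc, quantile and median-scaled fits also lacked CR-NIA replicate 1.

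**Figure D4:**
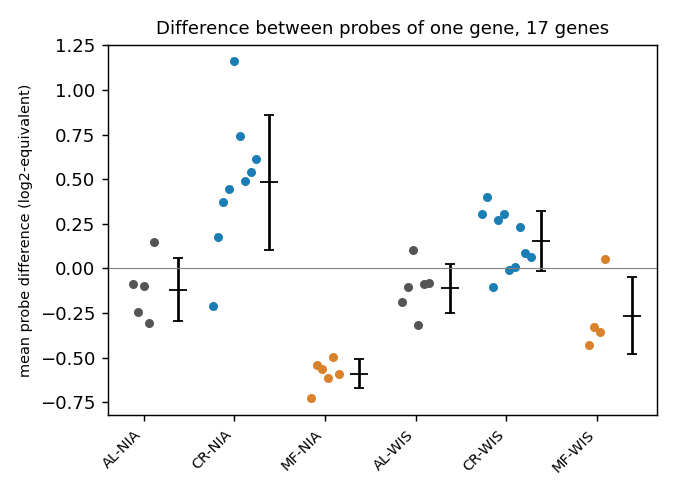
Mean difference between probes of 1 gene that were higher and those that were lower in CR-NIA against MF-NIA, over 17 genes (y axis, log2 units, centred over all libraries), per library and group, with the group mean and SD. The 6 MF-NIA libraries lie lowest, and CR-NIA has the highest mean, 0.48, which both follow in part from choosing the genes by this pair.

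Caloric restriction and meal feeding on WIS were compared in the same way. Usp2 rose 8.36-fold in CR-WIS (log2 3.06, SE 0.62, adjusted p = 0.00752, n = 10 CR and 4 MF), above all MF libraries in 9 of 10, with other probes at log2 0.95 (adjusted p = 0.00686) and 0.33 (adjusted p = 0.074). Per3 rose 2.06-fold (SE 0.21, adjusted p = 0.00696), Per2 2.69-fold (SE 0.30, adjusted p = 0.00952) and Ciart 3.71-fold (SE 0.41, adjusted p = 0.00952). Of 4 MF-WIS arrays, Usp2 and Ciart were detected on 2 and Per3 on 1, so these folds are taken against signals partly at background. Of 15 clock genes 5 rose and 1 fell, or 8 and 3 adjusted over the list alone. The set test gave adjusted p = 0.00346, and adjusted p = 0.756 with an estimated correlation. Pcsk4, a proprotein convertase, rose 2.9-fold (SE 0.33, adjusted p = 0.00952) and Aacs, which activates acetoacetate, 2.82-fold (SE 0.34, adjusted p = 0.0125). Ndrg1, a stress-response gene, was 2.79-fold lower (log2 -1.48, SE 0.25, adjusted p = 0.00152), below all MF libraries in 10 of 10, and Insig2 3.3-fold lower (SE 0.37, adjusted p = 0.00952), with 1 of its 2 other probes at adjusted p = 0.107. The amino acid decarboxylase Ddc was 3.14-fold lower (SE 0.41, adjusted p = 0.0217) and the tight junction gene Cldn1 2.9-fold lower (SE 0.36, adjusted p = 0.0148). Of 53 ribosomal protein genes 2 rose, or 12 adjusted over the list alone, Rps3a1 among them (1.49-fold, SE 0.14, adjusted p = 0.0159). Without AL-WIS replicate 1, 10 of the list rose, and without MF-WIS replicate 4, 1 did. That list had adjusted p = 3.93e-11, and adjusted p = 0.989 with an estimated correlation. The mean probe difference was 0.15 in CR-WIS and -0.27 in MF-WIS.

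In all, 268 genes changed in CR-WIS against MF-WIS, 108 higher and 160 lower, and 339 without the 3 libraries. The count was 99 and 66 without MF-WIS replicates 1 and 4, 134, 142, 453, 170 and 157 without CR-WIS replicates 1, 2, 3, 5 and 7, and 557 without AL-WIS replicate 1. Ciart, Per2, Cldn1 and Ddc lost their calls without MF-WIS replicate 1 (adjusted p 0.052, 0.0578, 0.0722 and 0.061), Aacs and Ddc without MF-WIS replicate 4 (0.139 and 0.128; Aacs at log2 0.92), and Rps3a1 without MF-WIS replicate 2 (0.0509). The share of higher calls, 40.3%, was 56.7% after neqc and 56.2% with quantile normalization.

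The diets were compared within each regimen to ask what the WIS food changed at a given feeding pattern. Beside its sucrose, WIS held more fat (24.4% against 17.7% of energy) and more energy per gram (3.927 against 3.418 kcal). Per the labels, AL-NIA mice ate more calories than any other group, so under AL the pair differs in intake too. An effect of sucrose cannot be told apart from these. Apoa4, an apolipoprotein of lipid-rich particles, rose on WIS 4.86-fold under AL (log2 2.28, SE 0.38, adjusted p = 0.00422, n = 6 WIS and 5 NIA) and 5.11-fold under CR (log2 2.35, SE 0.29, adjusted p = 5.43e-06, n = 10 and 9). In both regimens all WIS libraries lay above all NIA libraries. Under MF, Apoa4 lay 2.05 log2 units higher on WIS (SE 0.40, adjusted p = 0.0833, n = 4 and 6), a value looked up after the other regimens were seen. Cyp3a11, a drug-metabolizing hydroxylase, was 2.8-fold lower on WIS under CR (log2 -1.49, SE 0.22, adjusted p = 0.000102), in 10 of 10 libraries below all NIA libraries, and at 2.45-fold below NIA under AL (SE 0.29, adjusted p = 0.0685). Cyp2c55, of the same enzyme class, was detected on 2 of 10 CR-WIS arrays and was lower under CR by a measured 2.52-fold, taken against signals mostly at background (SE 0.22, adjusted p = 0.000458). It lay 2.62-fold below NIA under AL (SE 0.29, adjusted p = 0.0602) and 2.31-fold below under MF (SE 0.31, adjusted p = 0.222). Cyp2b10, induced through the receptor CAR, was not detected on any of the 10 CR-WIS arrays and on 8 of 8 CR-NIA arrays read, at least 1.51-fold lower (adjusted p = 0.00666).

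Of 19 CAR and PXR genes 5 fell on WIS under CR, or 8 adjusted over the list alone, with list adjusted p = 9.52e-05, and adjusted p = 0.775 with an estimated correlation. Without AL-WIS replicate 1, which is outside this pair, 8 fell over all genes. Under AL 0 passed over all genes and 3 fell adjusted over the list alone (list adjusted p = 7.55e-05, and adjusted p = 0.451 with an estimated correlation). The AL median of -0.42 was -0.19 without AL-WIS replicate 1 (list adjusted p = 0.0459). Under MF 0 passed over all genes and 7 fell adjusted over the list alone (list adjusted p = 8.71e-06, and adjusted p = 0.451 with an estimated correlation). The MF median of -0.72 was -0.47 without MF-WIS replicate 4. Near-identical Cyp2c and Cyp3a transcripts can share probes, so single members are uncertain. Also lower on WIS under CR were Csad, of taurine synthesis (2.37-fold, SE 0.29, adjusted p = 0.0123), the transferrin receptor gene Tfrc (2.03-fold, SE 0.24, adjusted p = 0.0135) and the vitamin E transfer protein Ttpa (1.91-fold, SE 0.17, adjusted p = 0.00168). The translation factor subunit Eif3c rose 1.65-fold (SE 0.13, adjusted p = 0.00173).

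Of 29 proteasome genes 6 fell on WIS under CR, or 8 adjusted over the list alone, among them Psmb3 (1.33-fold, SE 0.08, adjusted p = 0.00168), with list adjusted p = 1.79e-06, and adjusted p = 0.181 with an estimated correlation. Of 53 ribosomal protein genes 5 fell, or 5 with 1 rising adjusted over the list alone, among them Rpl36a (1.43-fold, SE 0.11, adjusted p = 0.00599). That list had adjusted p = 0.00106, and adjusted p = 0.933 with an estimated correlation. It lost its call without CR-NIA replicate 6 (0.0527) and with neqc or quantile normalization of the signals. The mean probe difference was 0.48 in CR-NIA, in part by the choice of its genes, and 0.15 in CR-WIS. Of 15 integrated stress response genes 1 rose, or 2 adjusted over the list alone (list adjusted p = 0.0176, and adjusted p = 0.139 with an estimated correlation), with the hormone gene Fgf21, detected on 3 of 8 CR-NIA arrays read, at 2.16-fold (SE 0.32, adjusted p = 0.0507). Without AL-WIS replicate 1, 4 of the 15 genes rose, and without CR-NIA replicate 1 or MF-WIS replicate 4, 2 did.

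Under AL, 20 macrophage markers lay higher on WIS at a median log2 of 0.77 and 0 passed, also adjusted over the list alone (list adjusted p = 0.000182, and adjusted p = 0.451 with an estimated correlation). Without AL-WIS replicate 1 the median was 0.19 and the list adjusted p 0.322. Lipogenesis genes under AL had a median log2 of -0.29 with 0 of 19 past the test and 0 adjusted over the list alone (list adjusted p = 0.0146, and adjusted p = 0.565 with an estimated correlation). In the list test without AL-WIS replicate 1 the lipogenesis list turned direction (adjusted p = 0.888) and its median shrank to -0.03, and without AL-NIA replicate 5 it lost its call.

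In all, 2 genes changed between diets under AL, Apoa4 and Tma7, a translation machinery-associated gene (1.86-fold higher, SE 0.17, adjusted p = 0.0178), with 1050 at an unadjusted p under 0.05 and 15 without the 3 libraries. That count was 1 without AL-NIA replicate 2 or 4 or AL-WIS replicate 1 or 6, where Tma7 lost its call (highest adjusted p = 0.116). It was 13, 5, 4 and 7 without AL-WIS replicate 4, CR-WIS replicate 4, MF-WIS replicate 3 and MF-WIS replicate 4. Under CR 223 changed, 119 higher and 104 lower, with 881 without the 3 libraries, 480 without CR-NIA replicate 1, 145 without CR-NIA replicate 4 and 427 without AL-WIS replicate 1. The share of higher calls under CR, 53.4%, was 44.2% after neqc, 39.9% with quantile normalization, 48% without the detection filter and 76.3% with median scaling. The neqc, quantile and median-scaled fits also lacked CR-NIA replicate 1. Under MF 0 changed by limma, with 843 at an unadjusted p under 0.05, 1 without the 3 libraries and 1 after neqc of the signals. It was 1, 10 and 2 without MF-NIA replicate 4, AL-WIS replicate 1 and CR-WIS replicate 4, and 2, 5 and 1 without MF-WIS replicates 2, 3 and 4.

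Whether the regimen effects differed between diets was tested by interaction terms. For CR, 3 genes differed, each at adjusted p = 0.0335 (limma). The CR effect was lower on WIS for Ccng1, a p53 target (log2 -0.90, SE 0.17). It was also lower for Sh3bgrl, an SH3 domain-binding protein-like gene (log2 -1.03, SE 0.21). For Rabggta, a Rab-modifying enzyme, the effect was higher (log2 0.71, SE 0.14). The call of Ccng1 rests on 1 of 3 probes, the others lying at log2 -0.38 (adjusted p = 0.503) and -0.59 (adjusted p = 0.215). Without the 3 libraries the count was 132 and Ccng1, Sh3bgrl and Rabggta kept their calls. None was called without AL-NIA replicate 1, 2 or 4, CR-NIA replicate 2, 4, 8 or 9, AL-WIS replicate 4, 5 or 6, or CR-WIS replicate 1, 8 or 9, where the count was 0 (limma; 805 at an unadjusted p under 0.05 with all libraries), and 1 without AL-NIA replicate 5 or CR-WIS replicate 7. The count was 53 without CR-NIA replicate 1, 7 without AL-WIS replicate 1, 6 without CR-WIS replicate 5 and 10 without MF-WIS replicate 4. Rabggta and Sh3bgrl lost their calls also without some of the other libraries, at adjusted p up to 0.111. For MF 0 genes differed by limma, with 771 at an unadjusted p under 0.05, and 0 without the 3 libraries.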

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

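The tests of cell type shares, of mislabelled libraries, of collection time and of probes in the paragraphs here were chosen only after the result was seen; so was the normalization test, though its bound was set before its value was computed. The random splits were planned. Of 68 tests for a library far from its group 11 found one, where chance finds about 1 in 20 groups, 3.4 here. All 11 fell on AL-WIS replicate 1, CR-NIA replicate 1 or MF-WIS replicate 4. CR-WIS replicate 3, described below, was not among them though it also differed from its group. The lists of 1 library move together and were chosen after their values were seen, so 3.4 is only a rough guide.

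AL-WIS replicate 1 stood far from the other 5 AL-WIS libraries, with list scores of 3.41 for macrophage markers, -1.87 for bile acid genes, -2.11 for CAR and PXR genes, -1.34 for gluconeogenesis, -1.54 for lipogenesis, -0.73 for oxidative phosphorylation and -1.63 for PPAR-alpha genes. A lower hepatocyte share alone would raise all other cell types alike, but macrophage markers rose 2.42 (SE 0.533 over the markers) more than endothelial ones. The macrophage list is among those that singled this library out, so the gap in part restates the pattern and does not decide. A lower hepatocyte share together with another change stays open, as the hepatocyte markers had a median shift of -0.61. A mislabelled library of another group stays open: its macrophage score lay 2.44 above the highest of the other 39 (their SD 0.492), but that highest library is AL-WIS too, so the gap restates the pattern. For the authors' normalization, the gap divided by the range was 0.624667 after neqc of the signals. This rounds to the critical value and lies just within the bound set beforehand for it as a cause. The gap itself, compared only afterwards, was larger after neqc (2.73 against 2.44). The scores of each AL-WIS library also matched the log2 signals of a column, centred and scaled per array, within 0.01. Such scaling treats all genes of an array alike, which argues against normalization as the cause of the macrophage rise. No biological explanation was tested, and more macrophages in this liver may be one.

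The library labelled CR-NIA replicate 1 stood apart with scores of -0.73 for clock genes, 0.32 for heat shock genes and 0.28 for unfolded protein response genes. A mislabelled AL-NIA library is a candidate explanation: over the genes called between CR and AL in WIS its score was -0.23, within the 5 AL-NIA libraries (-0.33 to -0.01) and below the other 8 CR-NIA libraries (0.10 to 0.37). The file header, with 6 AL-NIA and 8 CR-NIA columns, differs from the labels in the same direction. The other 8 CR-NIA libraries each matched a CR-NIA column within 0.01, and this library matched none (smallest largest difference 3.17). The 6 AL-NIA columns were not used, so a match there was not sought. A liver collected at another time of day would not account for this mismatch. For the scores alone it stays open: without clock genes the score was -0.22, but other genes can follow the time of day too. Variation between animals was not tested. CR-WIS replicate 3 had an AL-like score over the same genes too, -0.09, within the AL-WIS libraries (-1.11 to -0.05). It lay below the other CR-WIS libraries (0.11 or higher), with a clock score of -0.13 and Usp2 at -0.50. Its values matched a CR-WIS column within 0.01, so an AL-like score alone does not show a mislabelled library.

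Probes of 1 gene went opposite ways between CR-NIA and MF-NIA for 6.51% of genes with several called probes. A technical batch of CR-NIA alone is argued against, since the same genes' probe difference was 0.42 higher in CR-WIS than in MF-WIS (two-sided exact permutation p = 0.003996). RNA integrity or labelling that differs between regimens stays open, because transcript ends that change with the regimen could give the same pattern, and neither was tested here.

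MF-WIS replicate 4 lay at -0.012 for ribosomal protein genes, against -0.27 for the nearest of the other 3. The CR effect differed between diets for Ccng1 (log2 -0.90), Rabggta (0.71) and Sh3bgrl (-1.03), and in the list test for lipogenesis (median 0.39, adjusted p = 0.00989; adjusted p = 0.8 with an estimated correlation) and macrophage markers (median -0.63, adjusted p = 0.0153; adjusted p = 0.8 with an estimated correlation). Without AL-WIS replicate 1 these list p were 0.582 and 0.783, with medians of 0.10 and -0.09; the first also ended without AL-NIA replicate 5 and the second without AL-NIA replicate 2 or CR-NIA replicate 1. The MF effect differed in the list test for NRF2 genes (median 0.58, adjusted p = 1.11e-05), macrophage markers (-1.002, adjusted p = 0.000208) and endothelial markers (-0.49, adjusted p = 4.64e-07), with adjusted p = 0.565, 0.582 and 0.382 with an estimated correlation. NRF2 ended without MF-WIS replicate 4 (median 0.02, adjusted p 0.13), and was 0.33 without AL-WIS replicate 1. The macrophage list ended without AL-WIS replicate 1 (median -0.39, adjusted p 0.0529), and the endothelial median was -0.31 without MF-WIS replicate 4 (adjusted p 0.000345).

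For each count, 100 splits of the compared arrays were drawn, the real one included. Chance is unlikely where 1 split, the real one, reached the real count: CR against AL in NIA (885, highest other 357) and WIS (1139, 386), MF against AL in NIA (156, 4), and CR against MF in NIA (1220, 529) and WIS (268, 29). That is the lowest number 100 splits can give, and it was not corrected over the 11 counts. This is less clear for WIS against NIA under CR, where 2 splits did (223, highest other 420). For the diet by CR interaction 2 splits did too (3, highest other 142). These splits also mixed CR with AL arrays, which differed in many genes, so they cannot tell whether the interaction is due to chance. Chance cannot be excluded for MF against AL in WIS, where 18 splits reached the real count (3, highest other 1480). Nor can it for WIS against NIA under AL, where 11 splits did (2, highest other 207). With 0 genes by limma, all 100 splits did as well for WIS against NIA under MF (highest other 8; 843 at an unadjusted p under 0.05) and for the diet by MF interaction (highest other 186; 771). Splits calling 1480, 207, 142 or 186 genes point to a structure of the samples; which arrays carry it was not tested.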

How the results depend on the processing

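Leaving out 3 libraries together and neqc were chosen after seeing the data; of each change given here, the cause was not tested. Of 186 named gene results 0 reversed in any setting that covered them. Without the 3 libraries 163 kept their side of the threshold, and 112 did with the replicate number as a block. Genes whose call ended on removal of more than 4 single libraries were mostly left out beforehand. These numbers thus follow in part from that choice. By count of changed genes, neqc gave 0 for MF against AL in WIS, 396 for WIS against NIA under CR and 1 under MF. Quantile normalization alone gave 1, 454 and 1. Both, like median scaling, used the 34 signal columns, without AL-NIA and without the library labelled CR-NIA replicate 1. For WIS against NIA under CR, leaving out that library alone gave 480. The effect of the scaling cannot be told apart from its absence there. Median scaling gave 693 for CR against AL in WIS, 115 for CR against MF in WIS and 1 for WIS against NIA under MF. Without the detection filter, CR against MF had 2195 in NIA and 156 in WIS, and the diet by CR interaction 0 (805 at an unadjusted p under 0.05 in the limma fit with the filter). The mean of probes gave 4 for WIS against NIA under AL. Array weights gave 2085 for CR against AL in NIA, 910 and 16 for MF against AL in NIA and WIS, 2397 and 1262 for CR against MF, 26, 976 and 36 for WIS against NIA under AL, CR and MF, and 82 for diet by CR. Only the groups compared gave 362 for CR against AL in WIS, 316 and 0 for MF against AL, 0 and 438 for WIS against NIA under AL and CR, and 0 for diet by CR. Without the 3 libraries there were 2139, 529, 5, 2328, 15, 881, 1 and 132 for CR against AL in NIA, MF against AL in NIA and WIS, CR against MF in NIA, WIS against NIA under AL, CR and MF, and diet by CR.

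The replicate numbers were not taken as pairs. Correlations of same-numbered arrays were over 0.1 in 2 of 5 and 2 of 6 pairs for CR against AL in NIA and WIS, 3 of 5 and 1 of 4 for MF against AL, 4 of 6 and 0 of 4 for CR against MF, and 2 of 5, 0 of 9 and 2 of 4 for WIS against NIA under AL, CR and MF, ranging from -0.49 to 0.50. With the replicate number as a block, CR against AL had 323 in NIA and 272 in WIS, MF against AL 30 and 0, CR against MF in WIS 5, WIS against NIA 1 under AL and 120 under CR, and diet by CR 1; the block moved no other count by over 1.5 times.

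With 1 library left out, counts ran from 507 to 1422 and 423 to 1547 for CR against AL in NIA and WIS, 1 to 298 and 0 to 15 for MF against AL, and 877 to 1643 and 66 to 557 for CR against MF. They ran from 1 to 13, 145 to 480 and 0 to 10 for WIS against NIA under AL, CR and MF, 0 to 53 for diet by CR, and stayed at 0 for diet by MF. Reversed were the lipogenesis list for WIS against NIA under AL, without the 3 libraries (adjusted p = 0.852) or without AL-WIS replicate 1 (0.888; lowest value with 1 library left out 0.00126), and the macrophage list for diet by CR without the 3 libraries (0.896). With an estimated correlation 42 of 42 list calls ended, and with fry 24. A stricter detection filter and trended, robust moderation moved no count by over 1.5 times. The slide as a block was not run, as no slide is named. On these arrays, low signal over background limits the folds of dim genes.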

Other observations

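The comparisons of effects across regimens were written before the data were examined, and the count of genes shared by the 3 CR-NIA comparisons was chosen after the result was seen. Across 7958 genes, which are not independent replicates, the effects of CR and MF against the same AL-NIA libraries correlated at 0.49, where unchanged groups simulated against shared controls gave 0.59. Their covariance was 0.0372 against 0.0192 simulated, a difference of 0.0181, and with the AL libraries split the correlation was 0.23 (0.10 to 0.45 over 20 pairings). Of called genes 18 were higher in both and 30 lower in both, and since both effects share the AL-NIA libraries, neither count shows an excess. In WIS the correlation was 0.60, simulated 0.50, with covariance 0.0569 against 0.016 and a split correlation of 0.21 (-0.11 to 0.44). The 0.60 has a jackknife SE of 0.301 and was 0.37 without AL-WIS replicate 1, below the 0.50 simulated with all libraries. The effects of MF in NIA and in WIS, with no shared arrays, correlated at 0.24 (jackknife SE 0.165). The effects of the WIS diet under AL and CR correlated at 0.25 (SE 0.128), under AL and MF at 0.09 (SE 0.142; 0.04 without MF-NIA replicate 1 and 0.18 without MF-NIA replicate 4), and under CR and MF at 0.26 (SE 0.155).

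CR-NIA differed from AL-NIA, MF-NIA and CR-WIS in 54 genes called in all 3 comparisons, 30 higher and 24 lower in CR-NIA each time. All 3 comparisons hold the same CR-NIA libraries, so this count shows no excess by itself. Without CR-NIA replicate 1 there were 196 such genes, 87 higher and 109 lower.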
